A study of Mus musculus with 9 samples.

How the data were processed

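RNA bound to tagged ribosomes was sequenced from dorsal striatum of C57BL/6 mice at postnatal day 28. In the RiboTag method, Cre recombinase switches on a hemagglutinin-tagged ribosomal protein in a chosen cell type, and polyribosomes of that type are precipitated with an antibody to the tag. Here Cre was driven by the D1 dopamine receptor gene, so the target population was the D1 medium spiny neurons (MSNs) of the direct pathway. The 9 libraries formed 3 groups of 3, namely mice with Cre and the tag (control), mice that also carried floxed TrkB and showed stereotypy, and mice of that genotype without stereotypy. The labels describe the libraries of a group as biological triplicates and give no batch and no sex.

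The authors deposited 1 table per library with levels in CPM (reads of a gene scaled by the total of the library) for 47729 Ensembl gene identifiers. Per the submitters' processing notes, reads were aligned with TopHat to GRCm38. The read counter, its annotation and its use of strand are not given in the sources used here. In each library, 100% of the values above 0 were whole multiples of the value of 1 read within a tolerance of 0.1 reads, so whole reads were recovered. Totals ranged from 27103152 to 40578512 reads. A count of 0 allows a level of up to 0.0739 to 0.111 CPM (3 reads per library), which covers counting error only.

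Symbols, biotypes and positions came from GENCODE M21 on GRCm38, whose release may differ from the one the authors used. Of the identifiers, 47310 (99.12%) matched and 419 did not, and the unmatched ones held at most 0.0632% of the reads of a library. Since the use of strand is not known, overlapping and antisense genes could share reads, as could close paralogs; several genes abundant in brain or encoded by mitochondria are listed at 0 or close to it.

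Genes with at least 1 CPM in at least 3 libraries were tested (13695 genes). Values were transformed to log2(CPM + 1), which understates changes of low genes. All 9 libraries entered 1 limma fit (limma 3.58.1, R 4.3.3) with a mean for each of the 3 groups, a variance trend and 6 residual degrees of freedom. The contrasts were stereotypy against control, no stereotypy against control, stereotypy against no stereotypy and the mean of both TrkB-deleted groups against control, with a moderated F test for any difference among the 3 groups. P-values were adjusted by the Benjamini-Hochberg method and the threshold was 0.05. Of 37 gene lists written at the same time as the naming rule, 36 had at least 3 tested members and were tested with camera at its preset correlation of 0.01, adjusted over the lists of a comparison. Camera compares the members with all other tested genes, so a list called lower can have a median near or above 0. Camera with an estimated correlation and fry, which tests the members by themselves, were run as alternatives.

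Genes are named by a rule set before the data were examined. Among genes past the threshold, protein coding, with a mean of at least 5 CPM, a symbol that is not a model or clone name, and no overlap between the libraries of the groups compared, these are the 12 with the largest rise and the 12 with the largest fall per contrast. Ntrk2 and up to 2 members per direction of each list described were added, and for markers of other cell types the most abundant member. The text names a part of these genes, 1 gene that the rule picked is not reported here, and exceptions are marked where they occur.

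The tests were checked on simulated reads for the same 13695 genes. For stereotypy against no stereotypy, limma recovered 25.4% of the genes changed 1.5-fold, 56.7% of those changed 2-fold and 77.3% of those changed 3-fold. Unchanged genes made up 6.30%, 7.26%, 3.64% and 9.27% of its calls in the order stereotypy against control, no stereotypy against control, stereotypy against no stereotypy and both groups against control, and 15.3%, 21.8%, 12.9% and 17.9% of those of DESeq2, so the larger counts of DESeq2 came with more false calls there. Alternatives set at the same time as the naming rule were other pseudocounts (0.25 and 4), no filter, a mean of at least 5 CPM, median-of-ratios rescaling, quantile normalization, array weights, a replicate block, a covariate of glial and vascular markers, leaving out each library, fits to the 6 libraries compared, edgeR 4.0.16 with its quasi-likelihood test and DESeq2 1.42.0, the last pair on the recovered reads. Added after seeing the data were removal of a smooth trend over GC content and transcript length from each library, a covariate of D2 MSN, cortical and interneuron markers, leaving out a pair of libraries, and thinning of the reads to the smallest library.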

Results

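RNA precipitated with tagged ribosomes, targeted to D1 medium spiny neurons (MSNs), the direct-pathway output neurons of the dorsal striatum, was profiled in 3 groups of 3 libraries. These were control mice, TrkB-deleted mice with stereotypy (repetitive behavior) and TrkB-deleted mice without it. The libraries include none of RNA before precipitation, so enrichment for D1 MSN RNA was not measured. A change in level can therefore also reflect RNA of other cells in the precipitate. The total reads were 36535817, 35346341 and 32615356 in the controls, 27928813, 31117135 and 27103152 in the stereotypy group and 38688698, 35702420 and 40578512 in the group without stereotypy. Within a group, log2 levels correlated across genes at 0.980 to 0.995 (Pearson). As a check for a library deposited more than once, the lowest chi-square per degree of freedom of any pair was 14.5, with reads taken as independent, so each library was counted once.

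The first question was whether the targeted gene was lower in the deleted groups. Ntrk2 (ENSMUSG00000055254, GRCm38 chromosome 13, 58806569 to 59133970), the gene of the BDNF receptor TrkB, stood at 397 ± 84.8 CPM in the controls, 39.6 ± 4.85 CPM with stereotypy and 18.9 ± 4.67 CPM without (SD, n = 3 each). The remaining level was 9.98% of the control mean with stereotypy and 4.76% without. In limma the log2 change was -3.28 with stereotypy (SE 0.19, adjusted p = 3.81e-05) and -4.33 without (SE 0.19, adjusted p = 1.99e-06). All 6 libraries of the deleted groups lay below all 3 controls. Ntrk2 was higher with stereotypy than without by 1.05 on the log2 scale (SE 0.19, adjusted p = 0.0206). That call was lost without stereotypy replicate 2 (adjusted p = 0.0678), stereotypy replicate 3 (0.0825), no stereotypy replicate 1 (0.0610) or no stereotypy replicate 2 (0.0662). It was also lost, in alternatives chosen after seeing the data, without replicate 3 of both TrkB-deleted groups (0.0953), after removal of a trend over GC content and transcript length (0.0683) and with markers of other neurons as a covariate (0.0554). With glial and vascular markers as a covariate the difference was 0.70 (adjusted p = 0.136), and over all alternatives the adjusted p ranged from 1.89e-05 to 0.136. The log2 difference was 0.97, 1.03, 1.21 and 0.86 without those single libraries, 1.05 without the pair, 0.94 after removal of the trend and 1.29 with the other-neuron covariate, so its size lay near that of all libraries where the call was lost, other than with the glial and vascular covariate.

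**Figure D1:**
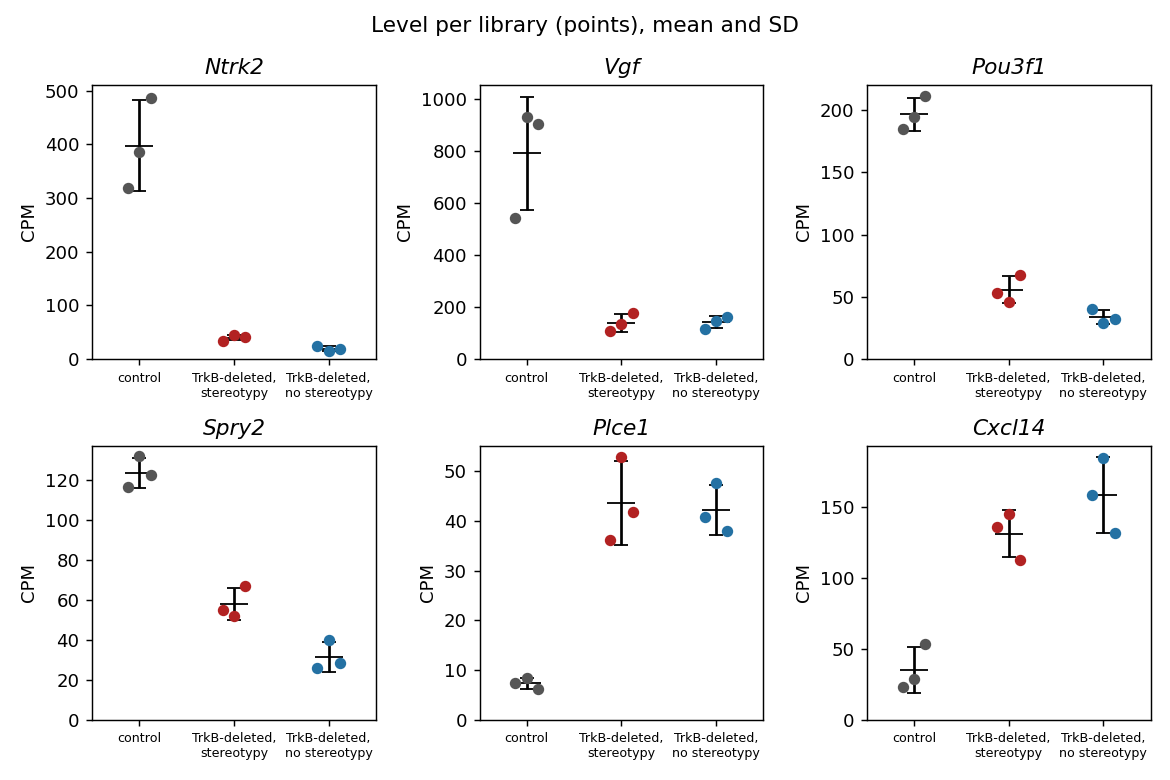
Level in CPM (vertical axes, linear from 0) of Ntrk2, Vgf, Pou3f1, Spry2, Plce1 and Cxcl14 in each library (points) by group, with the mean and SD over 3 libraries. Ntrk2, Vgf, Pou3f1 and Spry2 were lower in every TrkB-deleted library than in every control, and Plce1 and Cxcl14 were higher.

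The mean of both TrkB-deleted groups was then compared with the control to find what differed on average by genotype. Vgf (chromosome 5, 137026392 to 137033351), a neuropeptide precursor induced by neurotrophins, fell from 792 ± 217 CPM in the controls to 139.6 ± 34.2 CPM with stereotypy and 141 ± 22.6 CPM without (SD, n = 3 each). Its log2 change in limma was -2.47 (SE 0.19, adjusted p = 8.41e-05). The POU-domain transcription factor Pou3f1 changed by -2.17, the cyclin Ccnd2 by -2.04 and the clock gene Per2 by -1.66. Plce1 (chromosome 19, 38481109 to 38785030), a phospholipase C, rose from 7.33 ± 1.06 CPM to 43.6 ± 8.48 and 42.1 ± 4.99 CPM (SD, n = 3 each). The log2 change in limma was 2.39 (SE 0.14, adjusted p = 1.58e-05). The chemokine Cxcl14 rose from 35.2 CPM to 131 and 158 CPM. The axon guidance cue Ntn1 rose from 10.5 to 32.5 and 43.8 CPM, and Ceacam10, of the carcinoembryonic antigen family, from 0.284 to 9.34 and 7.74 CPM.

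Feedback targets of MAPK signalling were lower as a group. Of 14 tested members 10 fell, 0 rose and 4 did not pass (0 higher and 12 lower when adjusted over the list alone). The list had a median log2 change of -1.30, with camera adjusted p = 2.92e-16, and adjusted p = 0.172 with an estimated correlation. Spry2, an inhibitor of receptor tyrosine kinase signalling, fell from 124 ± 7.64 CPM to 57.8 ± 7.89 CPM with stereotypy and 31.2 ± 7.55 CPM without (SD, n = 3 each). In limma its log2 change was -1.53 (SE 0.13, adjusted p = 0.000175). Spred3, of a related family, fell from 29.6 to 6.28 and 6.41 CPM. Immediate early genes, which neuronal activity induces and which share Egr1 with the MAPK list, fell in 6 of 22, rose in 0 and did not pass in 16 (0 higher and 10 lower when adjusted over the list alone). These genes had a median log2 change of -0.59, with camera adjusted p = 6.36e-07, and adjusted p = 0.487 with an estimated correlation. Their median was -0.88 without control replicate 1, -0.93 without control replicate 2 and -0.25 without control replicate 3. The transcription factor Egr4 changed by -1.10 (adjusted p = 0.0284). Its call was lost without control replicate 3 (adjusted p = 0.0744), stereotypy replicate 2 (0.0595) or no stereotypy replicate 1 (0.0625), and without the filter (0.0949). In this list control replicate 3 stood apart, with Fos, a gene chosen after its values were seen, at 49.9 CPM against 6.68 and 7.89 CPM.

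Some lists of MSN genes were lower on average, while D1 and D2 MSN markers did not pass as lists. Of these 0 of 9 and 0 of 6 members passed in limma (3 and 1 at an unadjusted p under 0.05, and 0 called by edgeR). Markers of the striatal matrix compartment fell in 2 of 5, the transcription regulator Id4 (-0.57) and the calcium-binding protein Calb1 (-0.78), and rose in 0 (0 higher and 3 lower when adjusted over the list alone). Matrix markers had a median log2 change of -0.26, with camera adjusted p = 0.000670, and adjusted p = 0.172 with an estimated correlation. Genes shared by all MSNs fell in 5 of 23 and rose in 0 (1 higher and 7 lower when adjusted over the list alone). They had a median log2 change of -0.10, with camera adjusted p = 0.00194, and adjusted p = 0.557 with an estimated correlation. Their median was -0.0415 without control replicate 2, -0.0531 without no stereotypy replicate 3 and -0.0604 without replicate 3 of both TrkB-deleted groups. For stereotypy against control alone the list did not pass, with a median of 0.04, 1 higher, 1 lower and camera adjusted p = 0.304. Among its members the tyrosine phosphatase Ptpn5 fell from 891 ± 125 to 529 ± 47.3 and 513 ± 103 CPM (SD, n = 3 each). Dopamine and cAMP signalling genes fell in 4 of 31 and rose in 0 (1 higher and 6 lower when adjusted over the list alone). This list had a median log2 change of -0.05, with camera adjusted p = 0.00389, and adjusted p = 0.346 with an estimated correlation. Its median was -0.0954 with rescaling, 0.00577 without control replicate 1, -0.13 without control replicate 2 and -0.0201 without control replicate 3. Camera still called the list without control replicate 1 (adjusted p = 0.0147). It did not pass for stereotypy against control alone, with a median of 0.05, 0 higher, 1 lower and camera adjusted p = 0.153. One of its fallen genes was Rgs20, a regulator of G-protein signalling (-1.27, adjusted p = 0.000201).

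Axon guidance genes rose in 11 of 72 and fell in 0 (17 higher and 3 lower when adjusted over the list alone). The guidance list had a median log2 change of 0.26, with camera adjusted p = 0.00304, and adjusted p = 0.627 with an estimated correlation. It did not pass for stereotypy against control alone, with a median of 0.15, 3 higher, 2 lower and camera adjusted p = 0.255. The semaphorin Sema6a rose by 1.33 on the log2 scale. Astrocyte markers rose in 4 of 12 and fell in 0 (8 higher and 0 lower when adjusted over the list alone). Astrocyte markers had a median log2 change of 0.62, with camera adjusted p = 8.39e-05, and adjusted p = 0.405 with an estimated correlation. The glycolytic enzyme Aldoc rose by 0.57, and the most abundant marker, the bicarbonate transporter Slc4a4, stood at 275 ± 22.7, 394 ± 31.8 and 253 ± 23.1 CPM in the 3 groups (SD, n = 3 each). Oligodendrocyte and oligodendrocyte precursor markers were higher as lists, with 0 of 12 and 0 of 6 past the threshold in limma (3 at an unadjusted p under 0.05 and 0 called by edgeR in each, with 0 and 2 higher when adjusted over the list alone). Oligodendrocyte markers had a median log2 change of 0.61, with camera adjusted p = 0.0104, and adjusted p = 0.688 with an estimated correlation. Their call was lost without control replicate 1 (adjusted p = 0.158) and without control replicate 2 (0.0519). Their median was 0.38 without control replicate 1 and 1.05 without control replicate 3. Precursor markers had a median log2 change of 0.50, with camera adjusted p = 0.0107, and adjusted p = 0.487 with an estimated correlation. Microglia markers did not pass, with a median of 0.08, 1 higher, 0 lower and camera adjusted p = 0.753. With glial and vascular markers as a covariate some of the calls named for both groups ended, at the highest adjusted p over the alternatives for each. The log2 change with the covariate was -1.02 for Egr4 (adjusted p = 0.263, from -1.10), -0.62 for Calb1 (adjusted p = 0.168, from -0.78) and -0.50 for Ptpn5 (adjusted p = 0.191, from -0.78), so that of Egr4 stayed about as large. The call of Aldoc, which is itself among the markers, ended too (0.303). Since astrocyte markers were higher in the TrkB-deleted groups, the covariate can also take up a genotype difference. Calls lost with it cannot be laid to glial RNA.

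In total 784 of 13695 genes passed for both TrkB-deleted groups against control, 503 higher and 281 lower. With median-of-ratios rescaling there were 391 and 361, and with edgeR 340 and 389, so the higher share went from 64.2% to 52.0% and 46.6%. Of 36 lists 14 passed in camera with the preset correlation and 0 with an estimated one (4 at an unadjusted p under 0.05), and fry called 2. Fry called MAPK feedback targets and matrix markers. The gene count was 88 with glial and vascular markers as a covariate, 392 without the filter on low levels, 1326 with DESeq2 and 1283 with markers of other neurons as a covariate, the last chosen after seeing the data. It was 414 without stereotypy replicate 2, 439 without control replicate 1, 447 without no stereotypy replicate 1 and 516 without stereotypy replicate 1. Of the called genes picked by the naming rule, 38 of 47 kept their call whichever single library was left out, and 26 under every alternative.

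The stereotypy group was then compared with the control by itself. Stxbp3, a syntaxin-binding protein, rose from 5.82 ± 2.41 CPM in the controls to 22.7 ± 1.78 CPM with stereotypy (SD, n = 3 each). Its log2 change in limma was 1.86 (SE 0.22, adjusted p = 0.00234). The fatty acid oxidation enzyme Acadl rose from 2.84 to 13.5 CPM. Unc13b, a synaptic vesicle priming factor, rose from 16.5 to 55.6 CPM, a call lost without stereotypy replicate 2 (adjusted p = 0.0547, range over the alternatives 3.78e-07 to 0.404). Vgf changed by -2.48 on the log2 scale, Pou3f1 by -1.82, the vesicle amine transport homolog Vat1l by -1.65 and the formin Fmnl1 by -1.72. Of 14 MAPK feedback targets 6 fell, 0 rose and 8 did not pass (0 higher and 11 lower when adjusted over the list alone). The targets had a median log2 change of -0.996, with camera adjusted p = 3.98e-10, and adjusted p = 0.377 with an estimated correlation. Spred3 changed by -2.04 and Spry2 by -1.09. Immediate early genes were lower as a list, with 0 of 22 past the threshold in limma (9 at an unadjusted p under 0.05 and 1 called by edgeR) (1 higher and 3 lower when adjusted over the list alone). These genes had a median log2 change of -0.41, with camera adjusted p = 0.00199, and adjusted p = 0.718 with an estimated correlation. Their call was lost without control replicate 3 (adjusted p = 0.371) and with the covariate of other-neuron markers (0.0964). Their median was -0.13 without control replicate 3, -0.67 without stereotypy replicate 3 and -0.20 with the covariate of other-neuron markers.

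With glial and vascular markers as a covariate the calls of Plce1, Ceacam10, Acadl, Pou3f1 and Vat1l stayed in this comparison, and those of the other genes just named ended. The adjusted p was the highest over the alternatives for each. The log2 change with the covariate was 1.92 for Stxbp3 (adjusted p = 0.113, from 1.86), -1.73 for Fmnl1 (adjusted p = 0.0582, from -1.72), -2.24 for Spred3 (adjusted p = 0.0536, from -2.04) and -2.17 for Vgf (adjusted p = 0.0582, from -2.48), so these changes stayed about as large. It was 0.92 for Unc13b (adjusted p = 0.404, from 1.70) and -0.54 for Spry2 (adjusted p = 0.266, from -1.09), so these shrank. Unc13b also lost its call without replicate 3 of both TrkB-deleted groups (0.0544).

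Lists of astrocyte, oligodendrocyte, precursor and vascular markers were higher in the stereotypy libraries than in the controls, while microglia markers did not pass as a list, with a median of 0.32, 1 higher, 0 lower and camera adjusted p = 0.0613. Of 12 astrocyte markers 6 rose and 0 fell (9 higher and 0 lower when adjusted over the list alone). Astrocyte markers had a median log2 change of 0.77, with camera adjusted p = 1.18e-05, and adjusted p = 0.377 with an estimated correlation. The gap junction gene Gja1 rose from 2.96 ± 0.254 to 7.92 ± 0.733 CPM and the glutamate transporter Slc1a3 from 6.47 ± 0.707 to 16.2 ± 4.01 CPM (SD, n = 3 each). Both calls were lost without stereotypy replicate 2 (adjusted p = 0.0670 and 0.0730). With the covariate of glial and vascular markers, which holds both genes, they were lost as well (0.444 and 0.564). Of 11 vascular markers 2 rose and the smooth muscle gene Tagln fell (10 higher and 1 lower when adjusted over the list alone). Vascular markers had a median log2 change of 1.12, with camera adjusted p = 0.00391, and adjusted p = 0.718 with an estimated correlation. Of 6 oligodendrocyte precursor markers 1 rose and 0 fell (5 higher and 0 lower when adjusted over the list alone). These markers had a median log2 change of 0.73, with camera adjusted p = 0.00529, and adjusted p = 0.718 with an estimated correlation. Oligodendrocyte markers rose in 1 of 12 and fell in 0 (1 higher and 0 lower when adjusted over the list alone). Oligodendrocyte markers had a median log2 change of 0.63, with camera adjusted p = 0.0284, and adjusted p = 0.718 with an estimated correlation. Their call was lost without control replicate 1 (adjusted p = 0.276), without control replicate 2 (0.0745) and without stereotypy replicate 1 (0.133). Their median was 0.34 without control replicate 1, 0.41 without control replicate 2, 1.003 without control replicate 3 and 1.22 with the covariate of other-neuron markers.

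Of 7 mitochondrially encoded mRNAs 2 rose, the respiratory chain subunits mt-Nd5 and mt-Co1, and 0 fell (7 higher and 0 lower when adjusted over the list alone). The 7 mRNAs had a median log2 change of 1.05, with camera adjusted p = 0.00227, and adjusted p = 0.718 with an estimated correlation. Both gene calls were lost without control replicate 2 (adjusted p = 0.0683 and 0.0747), control replicate 3 (0.0679 and 0.0795), stereotypy replicate 1 (0.0804 and 0.0999) or stereotypy replicate 2 (0.116 and 0.122). That of mt-Nd5 was also lost without stereotypy replicate 3 (0.0615), that of mt-Co1 without no stereotypy replicate 1 (0.0519), and both without the filter (0.0802 and 0.0868) and with the covariate of glial and vascular markers (0.628 and 0.698), where the log2 changes were 0.72 and 0.43 against 1.40 and 0.99. Nuclear-encoded subunits of the respiratory chain were lower as a list relative to the other tested genes, with 0 of 73 members past the threshold in limma (7 at an unadjusted p under 0.05 and 1 called by edgeR, and 0 when adjusted over the list alone). Fry did not call them (adjusted p = 0.838). Against a median of 0.055 over all tested genes, they had a median log2 change of -0.05, with camera adjusted p = 0.00432, and adjusted p = 0.718 with an estimated correlation. The call was lost without control replicate 1 (adjusted p = 0.191) or stereotypy replicate 3 (0.427) and after removal of a trend over GC content and transcript length (0.0785), an alternative chosen after seeing the data. The median was -0.11 with rescaling, -0.0309 without control replicate 1, -0.0854 without control replicate 2, -0.10 without control replicate 3, -0.13 without stereotypy replicate 1, -0.0814 without stereotypy replicate 2, 0.0257 without stereotypy replicate 3, -0.0208 after removal of the GC and length trend, -0.0841 with the covariate of other-neuron markers and 0.0256 without replicate 3 of both TrkB-deleted groups.

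Markers of other neurons were lower as lists. D2 MSN markers were past the threshold in 0 of 6 in limma (1 at an unadjusted p under 0.05 and 1 called by edgeR), and interneuron markers in 1 of 16, which fell. The most abundant interneuron marker, Sst, was not called (-0.56, adjusted p = 0.208). D2 MSN markers had a median log2 change of -0.70, with camera adjusted p = 0.0104, and adjusted p = 0.718 with an estimated correlation. Interneuron markers had a median log2 change of -0.40, with camera adjusted p = 0.00432, and adjusted p = 0.718 with an estimated correlation. Cortical markers were past the threshold in 0 of 13 in limma (4 at an unadjusted p under 0.05 and 1 called by edgeR) (1 higher and 2 lower when adjusted over the list alone). The most abundant of them, Nrgn, changed by -0.06 (adjusted p = 0.828). Cortical markers had a median log2 change of -0.71, with camera adjusted p = 0.0259, and adjusted p = 0.718 with an estimated correlation. The cortical call was lost with rescaling (adjusted p = 0.0531), without control replicate 1 (0.111), without control replicate 3 (0.300), without stereotypy replicate 3 (0.108) and without replicate 3 of both TrkB-deleted groups (0.0718). It was also lost with the covariate of other-neuron markers (0.533), which holds these markers. In control replicate 3 the D2 receptor gene Drd2, chosen after its values were seen, stood at 74.8 CPM against 21.3 and 32.0 CPM in the other controls. Without that library the camera adjusted p became 0.273 for D2 MSN and 0.379 for interneuron markers. The D2 MSN median was -1.11 without control replicate 1 and -0.19 without control replicate 3. That of interneuron markers was -0.73 without control replicate 2, -0.0265 without control replicate 3 and -0.22 without stereotypy replicate 3. That of cortical markers was -1.22 without control replicate 2 and -0.22 without control replicate 3.

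For stereotypy against control 699 genes passed, 490 higher and 209 lower. With median-of-ratios rescaling there were 379 and 338, and with edgeR 321 and 322, so the excess of higher genes rested on the scaling. Of 36 lists 12 passed in camera with the preset correlation and 0 with an estimated one (3 at an unadjusted p under 0.05), and fry called 3. Those of fry were astrocyte markers, MAPK feedback targets and matrix markers, so the other lists that passed in camera were not called by fry. The gene count was 13 with glial and vascular markers as a covariate, 326 in a fit to the 6 libraries compared, 330 without the filter and 1522 with DESeq2. It was 124 without stereotypy replicate 2, 247 without stereotypy replicate 3, 283 without stereotypy replicate 1, 368 without control replicate 3, 397 without no stereotypy replicate 1 and 424 without no stereotypy replicate 2. Chosen after seeing the data, a covariate of other-neuron markers gave 1099 genes and leaving out replicate 3 of both TrkB-deleted groups gave 229. Of the called genes picked by the naming rule, 18 of 34 kept their call whichever single library was left out, and 6 under every alternative.

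The group without stereotypy was compared with the control in the same way. Ccnd2 fell from 202 ± 23.7 to 31.0 ± 4.01 CPM (SD, n = 3 each). The log2 change in limma was -2.66 (SE 0.16, adjusted p = 1.82e-05). Per2 fell from 48.9 to 10.5 CPM and the unconventional myosin Myo3b from 15.7 to 2.10 CPM. Ntn1 rose from 10.5 ± 0.619 to 43.8 ± 5.75 CPM (SD, n = 3 each). In limma its log2 change was 1.95 (SE 0.18, adjusted p = 0.000263). The small heat shock protein Cryab rose from 9.26 to 39.8 CPM and the adhesion glycoprotein Tpbg from 35.8 to 129 CPM. Of 72 axon guidance genes 15 rose, 2 fell and 55 did not pass (23 higher and 2 lower when adjusted over the list alone). The guidance list had a median log2 change of 0.29, with camera adjusted p = 9.12e-05, and adjusted p = 0.361 with an estimated correlation. The plexin receptor Plxna4 rose by 0.82. Of 54 presynaptic release genes 14 rose and 1 fell (18 higher and 1 lower when adjusted over the list alone). The release list had a median log2 change of 0.18, with camera adjusted p = 0.000214, and adjusted p = 0.361 with an estimated correlation. Its median was 0.28 without control replicate 3 and 0.11 with the covariate of other-neuron markers. The small GTPase Rab3b rose by 0.88 and the synaptotagmin Syt7 by 0.73, while the priming factor Unc13c changed by -1.08.

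Of 28 neuropeptide and peptide receptor genes 7 rose and 0 fell (10 higher and 2 lower when adjusted over the list alone). The peptide list had a median log2 change of 0.52, with camera adjusted p = 0.00121, and adjusted p = 0.361 with an estimated correlation. Its median was 0.33 without control replicate 1, 0.23 without control replicate 2, 0.82 without control replicate 3, 0.26 without no stereotypy replicate 3 and 0.11 with the covariate of other-neuron markers. The neuropeptide Y receptor Npy1r rose by 1.33, and Trh, the thyrotropin-releasing hormone gene, by 1.65, from 3.62 to 13.8 CPM. MAPK feedback targets fell in 10 of 14 and rose in 0 (0 higher and 13 lower when adjusted over the list alone). The targets had a median log2 change of -1.42, with camera adjusted p = 1.52e-14, and adjusted p = 0.206 with an estimated correlation. Spry2 changed by -1.97 and Spred3 by -2.02. Immediate early genes fell in 8 of 22 and rose in 0 (0 higher and 10 lower when adjusted over the list alone). They had a median log2 change of -0.75, with camera adjusted p = 7.23e-07, and adjusted p = 0.361 with an estimated correlation. Their median was -0.30 without control replicate 3. Among them the scaffold gene Homer1 changed by -1.33 and the transcription factor Egr1 by -1.03. Both calls were lost without no stereotypy replicate 1 (adjusted p = 0.0556 and 0.0599) and without the filter (0.0547 and 0.0550), and that of Homer1 also without no stereotypy replicate 2 (0.0527).

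Genes shared by all MSNs fell in 6 of 23 and rose in 0 (0 higher and 6 lower when adjusted over the list alone). They had a median log2 change of -0.20, with camera adjusted p = 1.01e-05, and adjusted p = 0.361 with an estimated correlation. Their median was -0.13 without no stereotypy replicate 3. The phosphoprotein genes Arpp21 and Arpp19 changed by -0.72 and -0.65. Matrix markers fell in 3 of 5 and rose in 0 (0 higher and 3 lower when adjusted over the list alone). Matrix markers had a median log2 change of -0.41, with camera adjusted p = 0.000945, and adjusted p = 0.206 with an estimated correlation. Dopamine and cAMP signalling genes fell in 7 of 31 and rose in 2 (2 higher and 11 lower when adjusted over the list alone). This list had a median log2 change of -0.16, with camera adjusted p = 0.000725, and adjusted p = 0.206 with an estimated correlation.

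Markers of D1 MSNs, astrocytes and oligodendrocytes passed as lists too without stereotypy. Microglia markers did not, with a median of -0.22, 0 higher, 0 lower and camera adjusted p = 0.156, nor did oligodendrocyte precursor markers, with a median of 0.29, 0 higher, 0 lower and camera adjusted p = 0.120 (in each list 1 at an unadjusted p under 0.05 and 0 called by edgeR). D1 MSN markers were lower as a list, with 0 of 9 past the threshold in limma (6 at an unadjusted p under 0.05 and 2 called by edgeR) (1 higher and 3 lower when adjusted over the list alone). D1 markers had a median log2 change of -0.42, with camera adjusted p = 0.0232, and adjusted p = 0.492 with an estimated correlation. The call was lost without control replicate 1 (adjusted p = 0.0858), without no stereotypy replicate 3 (0.264), with the covariate of other-neuron markers (0.125) and without replicate 3 of both TrkB-deleted groups (0.262). The D1 median was -0.28 without control replicate 1. Astrocyte markers rose in 1 of 12 and fell in 0 (2 higher and 0 lower when adjusted over the list alone). Astrocyte markers had a median log2 change of 0.39, with camera adjusted p = 0.0353, and adjusted p = 0.522 with an estimated correlation. This call was lost without control replicate 1 (adjusted p = 0.0605), without control replicate 2 (0.0948), without no stereotypy replicate 1 (0.135), without no stereotypy replicate 3 (0.0847), with the covariate of other-neuron markers (0.126) and without replicate 3 of both TrkB-deleted groups (0.0910). The astrocyte median was 0.19 without no stereotypy replicate 1. Oligodendrocyte markers were higher as a list, with 0 of 12 past the threshold in limma (2 at an unadjusted p under 0.05 and 0 called by edgeR) (0 higher and 0 lower when adjusted over the list alone). Oligodendrocyte markers had a median log2 change of 0.53, with camera adjusted p = 0.0299, and adjusted p = 0.675 with an estimated correlation. That call was lost without control replicate 1 (adjusted p = 0.229), without control replicate 2 (0.129), without no stereotypy replicate 3 (0.389), with the covariate of other-neuron markers (0.372) and without replicate 3 of both TrkB-deleted groups (0.396). The oligodendrocyte median was 0.31 without control replicate 1, 0.87 without control replicate 3, 0.85 without no stereotypy replicate 2, 0.22 without no stereotypy replicate 3 and 0.17 with the covariate of other-neuron markers.

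Cortical excitatory neuron markers rose in 2 of 13 and fell in 0 (3 higher and 0 lower when adjusted over the list alone). The most abundant of them, Nrgn, was not called (0.17, adjusted p = 0.544). The list had a median log2 change of 0.49, with camera adjusted p = 0.0492, and adjusted p = 0.675 with an estimated correlation. The camera call was lost without control replicate 2 (adjusted p = 0.705), stereotypy replicate 2 (0.0509) or no stereotypy replicate 3 (0.511), with the replicate block (0.0521) and after removal of a trend over GC content and transcript length (0.0893). It was also lost without replicate 3 of both TrkB-deleted groups (0.403, median 0.0630). With the covariate of other-neuron markers, which holds these markers, the adjusted p was 0.740 (median -0.0114). The median was 0.0296 without control replicate 2, 0.88 without control replicate 3 and 0.0630 without no stereotypy replicate 3. In no stereotypy replicate 3 the vesicular glutamate transporter Slc17a7 stood at 1140 CPM against 506 and 475 CPM in the others of its group. Mitochondrially encoded mRNAs were lower as a list, with 0 of 7 past the threshold in limma (1 at an unadjusted p under 0.05 and 1 called by edgeR, and 0 when adjusted over the list alone). The 7 mRNAs had a median log2 change of -0.63, with camera adjusted p = 0.0146, and adjusted p = 0.635 with an estimated correlation. That call was lost without control replicate 1 (adjusted p = 0.229) or no stereotypy replicate 2 (0.0590), and after removal of a trend over GC content and transcript length (0.0839), an alternative chosen after seeing the data. The median of these mRNAs was -0.14 without control replicate 1, -0.996 without control replicate 3, -0.41 without no stereotypy replicate 2 and -0.37 after removal of the GC and length trend. Nuclear-encoded subunits of the respiratory chain rose in 2 of 73 and fell in 0 (0 higher and 0 lower when adjusted over the list alone). The nuclear subunits had a median log2 change of 0.11, with camera adjusted p = 0.0207, and adjusted p = 0.701 with an estimated correlation. This call was lost without control replicate 2 (adjusted p = 0.0693) and without control replicate 3 (0.225). The nuclear subunit median was 0.0629 without control replicate 3.

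For no stereotypy against control 927 genes passed, 515 higher and 412 lower. With edgeR there were 411 and 493, so that the higher share went from 55.6% to 45.5%. Of 36 lists 20 passed in camera with the preset correlation and 0 with an estimated one (4 at an unadjusted p under 0.05), and fry called 3. The lists called by fry were MAPK feedback targets, matrix markers, and dopamine and cAMP signalling genes. The gene count was 316 without no stereotypy replicate 1, 448 without no stereotypy replicate 2 and 474 without control replicate 1. It was 575 in a fit to the 6 libraries compared, 484 without the filter, 1873 with array weights and 1509 with DESeq2. Of the called genes picked by the naming rule, 44 of 61 kept their call whichever single library was left out, and 44 under every alternative.

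Both comparisons with the control called 174 genes higher and 95 lower in common, and 0 genes in opposite directions by limma (83 at an unadjusted p under 0.05, and 1 by edgeR). Plce1, Ceacam10 and Cxcl14 were among the higher ones, and Vgf, Pou3f1 and Spred3 among the lower. Independent lists would share 18.4 and 6.29 genes, and simulated unchanged groups against shared simulated controls shared 0 genes by limma in each of 50 simulations. No gene was changed in them, so this 0 cannot show what the shared controls add among changed genes. Across genes, which are not independent replicates, the log2 changes had a covariance of 0.0548 against a mean of 0.0195 in the simulations, and a correlation of 0.445 against 0.499. Both changes had the same sign in 59.1% of genes, against 66.6% in the simulations. The 3 controls are too few to be divided between the comparisons. The shared count was 9 with glial and vascular markers as a covariate, 97 without stereotypy replicate 2, 126 without no stereotypy replicate 1, 133 without stereotypy replicate 1, 150 without no stereotypy replicate 2 and 154 without stereotypy replicate 3.

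The last comparison asked what differed between TrkB-deleted mice with and without stereotypy. Its calls of single genes did not last, since each gene named here lost its call when stereotypy replicate 3, no stereotypy replicate 1 or no stereotypy replicate 2 was left out. All 7 tested mitochondrially encoded mRNAs were higher with stereotypy (7 higher and 0 lower when adjusted over the list alone). The 7 mRNAs had a median log2 change of 1.74, with camera adjusted p = 1.09e-05, and adjusted p = 0.517 with an estimated correlation. Among them mt-Nd5 stood at 321 ± 56.4 against 79.0 ± 20.6 CPM (SD, n = 3 each). Its log2 change in limma was 2.03 (SE 0.30, adjusted p = 0.0154). With glial and vascular markers as a covariate it was 1.52 (adjusted p = 0.0634). There mt-Nd1, mt-Nd2 and mt-Nd4 changed by 1.24, 1.17 and 1.29 (adjusted p = 0.206, 0.341 and 0.231), from 1.53, 1.83 and 1.74. Nuclear-retained and long non-coding RNAs, given below, were higher in the same comparison (median 1.53). Whether the 7 mRNAs were bound to tagged ribosomes was not tested. Nuclear-encoded subunits of the respiratory chain were lower in 6 of 73 and higher in 1 (1 higher and 13 lower when adjusted over the list alone). The nuclear subunits had a median log2 change of -0.20, with camera adjusted p = 7.90e-06, and adjusted p = 0.524 with an estimated correlation. Their median was -0.11 without stereotypy replicate 3 and -0.13 after removal of the GC and length trend. Atp5d, a subunit of ATP synthase, differed by -0.53 and the acyl carrier subunit Ndufab1 by 0.76.

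Dgkb, a diacylglycerol kinase abundant in striatum, was higher with stereotypy, at 1122 ± 319 against 364 ± 27.8 CPM (SD, n = 3 each). The log2 change in limma was 1.58 (SE 0.23, adjusted p = 0.0154). Slc17a7 was lower, at 175 ± 50.2 against 707 ± 375 CPM (SD, n = 3 each), a log2 change of -1.93 (adjusted p = 0.0246). Cryab stood at 10.7 against 39.8 CPM. With the covariate of other-neuron markers, which holds Slc17a7, the log2 change was -0.67 for Slc17a7 (adjusted p = 0.0651). It was -0.86 for Cryab (0.0638, from -1.76) and 1.63 for Dgkb (0.0554), so those of Slc17a7 and Cryab shrank. Over all alternatives the adjusted p ranged from 7.54e-05 to 0.0835 for mt-Nd5, 1.10e-09 to 0.0835 for Dgkb and 0.00239 to 0.124 for Slc17a7.

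Markers of other neurons were lower with stereotypy. Cortical markers were lower in 2 of 13 and higher in 0 (0 higher and 4 lower when adjusted over the list alone). Cortical markers had a median log2 change of -0.98, with camera adjusted p = 8.23e-05, and adjusted p = 0.517 with an estimated correlation. Their median was -0.57 without no stereotypy replicate 3 and -0.48 without replicate 3 of both TrkB-deleted groups. The most abundant cortical marker, Nrgn, was not called (-0.24, adjusted p = 0.310). Interneuron markers were lower in 2 of 16 and higher in 0 (0 higher and 4 lower when adjusted over the list alone). Interneuron markers had a median log2 change of -0.92, with camera adjusted p = 5.98e-05, and adjusted p = 0.517 with an estimated correlation. The interneuron median was -0.55 without no stereotypy replicate 3. The most abundant interneuron marker, Sst, was not called (-0.72, adjusted p = 0.0904). D2 MSN markers were lower in 1 of 6 and higher in 0 (0 higher and 6 lower when adjusted over the list alone). D2 MSN markers had a median log2 change of -1.26, with camera adjusted p = 0.000774, and adjusted p = 0.517 with an estimated correlation. The most abundant D2 marker, the enkephalin precursor Penk, stood at 203 ± 44.1 against 489 ± 164 CPM (SD, n = 3 each, adjusted p = 0.0539).

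Beside these markers, presynaptic release genes were lower in 10 of 54 and higher in 2 (3 higher and 19 lower when adjusted over the list alone). The release list had a median log2 change of -0.19, with camera adjusted p = 5.98e-05, and adjusted p = 0.517 with an estimated correlation. Neuropeptide and peptide receptor genes were lower in 5 of 28 and higher in 1 (4 higher and 10 lower when adjusted over the list alone). The peptide list had a median log2 change of -0.69, with camera adjusted p = 0.000818, and adjusted p = 0.517 with an estimated correlation. Its median was -0.45 without no stereotypy replicate 3, 0.0476 with the covariate of other-neuron markers and -0.34 without replicate 3 of both TrkB-deleted groups. Trh stood at 4.94 against 13.8 CPM, a log2 change of -1.32 that became -0.86 with the covariate of other-neuron markers (adjusted p = 0.0894). With markers of other neurons as a covariate, an alternative chosen after seeing the data, the camera adjusted p was 0.0595 for presynaptic release (range over the alternatives 5.84e-07 to 0.517), with a median of -0.12. It was 0.341 for peptides (range 3.74e-05 to 0.517), a list that shares genes with the covariate.

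D1 MSN markers were higher with stereotypy in 2 of 9, Drd1 and the sugar transporter Slc35d3, and lower in 0 (5 higher and 0 lower when adjusted over the list alone). D1 markers had a median log2 change of 0.49, with camera adjusted p = 0.0103, and adjusted p = 0.517 with an estimated correlation. Their median was 0.19 with the covariate of other-neuron markers. The call was lost without no stereotypy replicate 3 (adjusted p = 0.109), without replicate 3 of both groups (0.134) and with the covariate of other-neuron markers (0.592). The dopamine D1 receptor gene Drd1 stood at 887 ± 60.4 CPM with stereotypy, 599 ± 73.9 CPM without and 805 ± 105 CPM in the controls (SD, n = 3 each). With the covariate of other-neuron markers the log2 change of Drd1 was 0.27 (adjusted p = 0.155), from 0.57. Of 14 MAPK feedback targets 3 were higher with stereotypy than without and 0 lower (3 higher and 0 lower when adjusted over the list alone). The targets had a median log2 change of 0.29, with camera adjusted p = 0.0181, and adjusted p = 0.520 with an estimated correlation. Spry2 was higher by 0.88 and Spred1 by 1.10. The list's call was lost without stereotypy replicate 3 (adjusted p = 0.0956) or replicate 3 of both groups (0.132, range over the alternatives 0.000579 to 0.520). The MAPK median was 0.53 after removal of the GC and length trend and 0.70 with the covariate of other-neuron markers.

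Genes shared by all MSNs were higher with stereotypy than without in 7 of 23 and lower in 0 (11 higher and 0 lower when adjusted over the list alone). They had a median log2 change of 0.20, with camera adjusted p = 0.00230, and adjusted p = 0.517 with an estimated correlation. The call was lost without no stereotypy replicate 3 (adjusted p = 0.174), with the covariate of other-neuron markers (0.708) and without replicate 3 of both TrkB-deleted groups (0.253). Their median was 0.0659 without no stereotypy replicate 3 and 0.0689 with the covariate of other-neuron markers. Axon guidance genes were lower in 9 of 72 and higher in 1 (5 higher and 16 lower when adjusted over the list alone). The guidance list had a median log2 change of -0.22, with camera adjusted p = 0.00657, and adjusted p = 0.520 with an estimated correlation. That call was lost without stereotypy replicate 1 (adjusted p = 0.0534) and with the covariate of other-neuron markers (0.978). Its median was -0.14 without stereotypy replicate 3, -0.11 without no stereotypy replicate 3, 0.0701 with the covariate of other-neuron markers and -0.0664 without replicate 3 of both TrkB-deleted groups.

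Astrocyte, microglia and vascular markers were also higher with stereotypy. Astrocyte markers were higher in 3 of 12 and lower in 0 (6 higher and 0 lower when adjusted over the list alone). Astrocyte markers had a median log2 change of 0.50, with camera adjusted p = 0.0181, and adjusted p = 0.517 with an estimated correlation. That call was lost without no stereotypy replicate 2 (adjusted p = 0.0922, range over the alternatives 0.000927 to 0.517). The astrocyte median was 0.32 without no stereotypy replicate 2. Microglia markers were higher in 2 of 12 and lower in 0 (2 higher and 0 lower when adjusted over the list alone). Microglia markers had a median log2 change of 0.56, with camera adjusted p = 0.00257, and adjusted p = 0.517 with an estimated correlation. Vascular markers were higher in 3 of 11 and lower in 0 (8 higher and 0 lower when adjusted over the list alone). Vascular markers had a median log2 change of 1.12, with camera adjusted p = 0.00152, and adjusted p = 0.517 with an estimated correlation. Oligodendrocyte markers did not pass as a list, with a median of 0.07, 0 higher, 0 lower and camera adjusted p = 0.866, nor did oligodendrocyte precursor markers, with a median of 0.40, 0 higher, 0 lower and camera adjusted p = 0.139. Nuclear-retained and long non-coding RNAs were higher in 3 of 7 and lower in 0 (5 higher and 0 lower when adjusted over the list alone). These RNAs had a median log2 change of 1.53, with camera adjusted p = 0.00323, and adjusted p = 0.517 with an estimated correlation. Their median was 0.83 with the covariate of other-neuron markers. The nuclear RNA Malat1 was higher by 1.61, and by 0.83 with that covariate (adjusted p = 0.267). The call of this list was lost with the covariate of other-neuron markers (adjusted p = 0.148, range over the alternatives 0.000225 to 0.517).

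**Figure D2:**
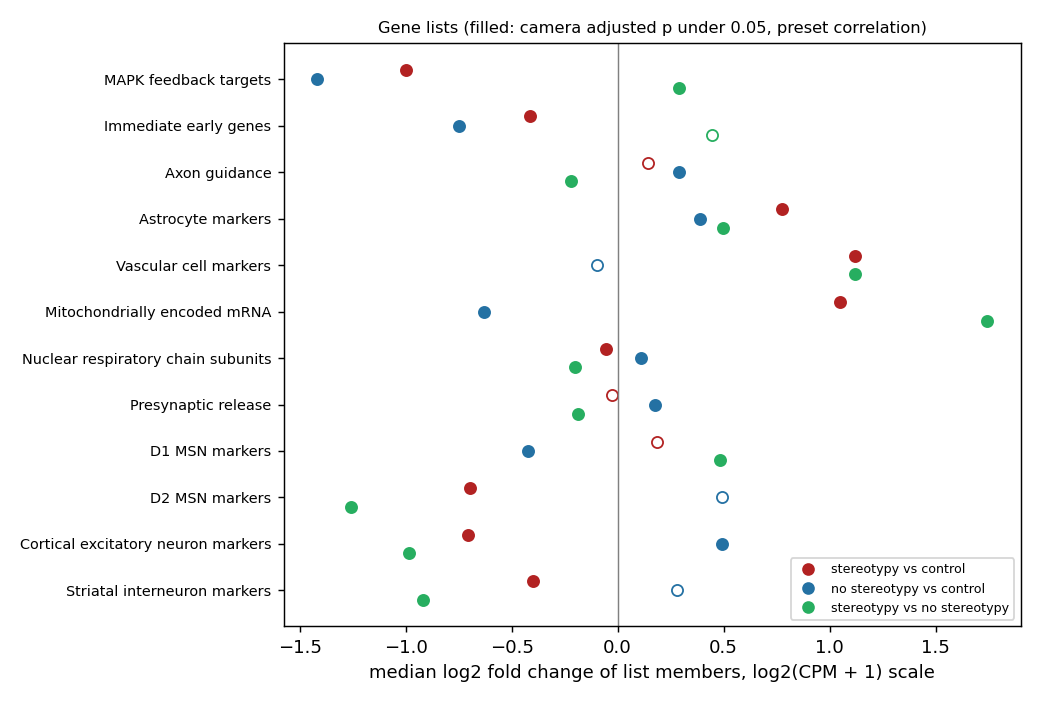
Median log2 fold change (horizontal axis, log2(CPM + 1) scale) of the members of 12 gene lists (vertical axis) in 3 comparisons (colors), filled where the camera adjusted p with the preset correlation was under 0.05; with an estimated correlation 0 lists passed in camera, while fry passed some against the control. MAPK feedback targets lie at -1.42 for no stereotypy against control, and mitochondrially encoded mRNAs at 1.74 for stereotypy against no stereotypy.

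For stereotypy against no stereotypy 1398 genes passed, 905 higher and 493 lower. With median-of-ratios rescaling there were 787 and 600, and with edgeR 778 and 557, so the higher share went from 64.7% to 56.7% and 58.3%. The count rested on single libraries. By limma and by edgeR it was 0 without stereotypy replicate 3, without no stereotypy replicate 1 or without no stereotypy replicate 2. In limma 2848, 2915 and 3084 genes then had an unadjusted p under 0.05, against 4089 with all libraries, and the lowest adjusted p was 0.0730, 0.0610 and 0.0561. The count was 1 without stereotypy replicate 2 and 799 without stereotypy replicate 1. It was 376 with glial and vascular markers as a covariate, 572 without the filter, 4698 with array weights and 2343 with DESeq2. Chosen after seeing the data, removal of a trend over GC content and transcript length left 7 genes, and a covariate of other-neuron markers left 0 by limma and edgeR (3655 at an unadjusted p under 0.05). Of 36 lists 16 passed in camera with the preset correlation and 0 with an estimated one (0 at an unadjusted p under 0.05), and fry called 0.

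The F test for any difference among the 3 groups called 1918 genes in limma and 1896 in edgeR. The count was 545 without no stereotypy replicate 1, 685 without no stereotypy replicate 2, 687 without stereotypy replicate 2, 783 without stereotypy replicate 3 and 1169 without stereotypy replicate 1. It was 839 without the filter, 965 with glial and vascular markers as a covariate, 4918 with array weights, 3322 with DESeq2 and, as an alternative chosen after seeing the data, 1126 after removal of the trend over GC content and transcript length.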

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

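The tests of glial markers and of astrocyte RNA were chosen only after the result was seen, and removal of a trend over GC content and transcript length and thinning of the reads were chosen after seeing the data, as was the test at an unadjusted p. The measured levels were flagged as differing between the groups with and without stereotypy for Ntrk2 (1.05 higher with stereotypy on the log2 scale, a call lost in 8 of 25 settings, with adjusted p up to 0.136) and for 3 lists with camera calls of opposite direction against the control. These were mitochondrially encoded mRNA (median difference 1.74), cortical excitatory neuron markers (-0.98) and nuclear respiratory chain subunits (-0.20), each by camera with its preset correlation and none with an estimated one. With single libraries left out these medians ranged from 1.51 to 1.90, -1.35 to -0.569 and -0.249 to -0.110. The calls for stereotypy and for no stereotypy against control were kept in 14 and 11 of 16 settings for mitochondrial mRNA, 8 and 7 of 16 for cortical markers and 10 and 12 of 16 for nuclear subunits. With single libraries left out, the medians against the control were 0.800 to 1.56 and -0.996 to -0.138, -1.22 to -0.219 and 0.0296 to 0.876, and -0.133 to 0.0257 and 0.0629 to 0.150, so for nuclear subunits the direction with stereotypy did not hold. Each pairwise difference rested on 3 libraries per group. Whether the mitochondrially encoded mRNAs were bound to tagged ribosomes was not tested.

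Across genes, the stereotypy against no stereotypy change followed GC content (Spearman rho -0.57, against -0.31 for stereotypy and 0.32 for no stereotypy against control; genes are not independent replicates). The rho of GC content with the deviation of a library from the mean of all libraries was -0.23, 0.22 and -0.06 in the controls, -0.28, -0.38 and -0.50 with stereotypy and 0.60, 0.51 and 0.05 without, in replicate order, so a difference in preparation that followed the groups stays open, as the labels give no batch. Removing a trend over GC content and length left 0.501% of the called genes called in the same direction, while a median share of 0.609 of their log2 change was left (quartiles 0.449 and 0.794). The median size went from 0.57 to 0.34 and the median SE from 0.13 to 0.11. At the largest unadjusted p of a called gene before removal (0.00510), 418 of 1398 called genes still passed (29.9%), so most calls ended with larger p values and the rest with the adjustment. On the rule for this test the loss of calls went with the trend, which may account for calls and part of the differences. The share left was taken over genes picked as called in these same data, which also hold chance deviations. It therefore cannot tell whether the trend was the whole of the differences. After removal 702 genes were called for stereotypy and 959 for no stereotypy against control, 521 of the 699 and 737 of the 927 called before among them. Library size is argued against, since 92.4% of the called genes stayed called after thinning to equal reads.

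D2 MSN, cortical and interneuron markers were lower with stereotypy (median of 35 markers -1.08). A lower share of all other cell types is argued against, because glial and vascular markers were higher (median 0.49, quartiles 0.10 and 0.80). The GC and length trend is argued against as well, since the median was -1.03 after its removal. A difference in the share of other neurons' RNA, from dissection or precipitation, and a difference between the mice stay open. D1 MSN markers (median 0.49) and genes shared by all MSNs (0.20) went the other way. With a covariate of the other-neuron markers 0 genes were called between the TrkB-deleted groups by limma and edgeR (3655 at an unadjusted p under 0.05 in limma). Built from the same markers, that covariate cannot tell these explanations apart.

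The higher Ntrk2 with stereotypy could come from astrocyte RNA, since astrocytes express Ntrk2. Ntrk2 per summed CPM of 9 astrocyte markers low in the controls was 0.721 ± 0.0896 with stereotypy and 0.523 ± 0.0199 without (SD, n = 3 each), a ratio of 1.38 that leaves this explanation open for part of the difference. The GC and length trend is argued against, because the log2 change was 0.94 after its removal, although the adjusted p became 0.0683 (range over the alternatives 1.89e-05 to 0.136). The SE was 0.18 from 0.19 and the unadjusted p 0.000309 from 0.000178, so this call ended mostly with the adjustment. Incomplete deletion was not tested.

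Chance was weighed by other splits of the libraries. For both TrkB-deleted groups against control, 1 of 100 splits, the real one, gave as many genes (784, highest other 300), and for the F test also 1 of 100 (1918, highest other 121). These were drawn from 840 and 280 possible splits, and other genotype splits could keep the real controls. The small share argues against chance for these counts without excluding it. For the pairwise comparisons the 10 splits are too few for a share under 0.05.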

How the results depend on the processing

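Removal of the GC and length trend, the covariate of other-neuron markers, the joint omission of replicate 3 of both TrkB-deleted groups, thinning of the reads, and all alternatives for the overlap except its threshold were chosen after seeing the data. For the changes below the cause was not tested. Counts are in the order stereotypy against control, no stereotypy against control, stereotypy against no stereotypy, both TrkB-deleted groups against control and the F test. Under pseudocounts of 0.25 and 4, a mean of at least 5 CPM, rescaling, quantile normalization, edgeR, thinning and the replicate block, all 5 counts stayed within 1.5 times their value. Whether the replicate numbers pair the libraries stayed open, since 4 of 9 pairs with the same number in different groups correlated above 0.1 after group means were removed, while 7 of 9 libraries correlated best with one of their own number. With the replicate block the counts were 917, 1099, 1788, 880 and 2352. Without the filter, where more genes were tested, they were 330, 484, 572, 392 and 839, and with DESeq2 1522, 1509, 2343, 1326 and 3322. The glial and vascular covariate gave 13 for stereotypy against control, 376 for stereotypy against no stereotypy, 88 for both groups against control and 965 for the F test. Some of its markers differed between the groups, so these falls can include group differences taken up by the covariate. Array weights gave 1873 for no stereotypy against control, 4698 between the TrkB-deleted groups and 4918 for the F test. The other-neuron covariate gave 1099 for stereotypy against control, 0 between the TrkB-deleted groups and 1283 for both groups against control, and removal of the GC and length trend gave 7 between the TrkB-deleted groups and 1126 for the F test. Without replicate 3 of both TrkB-deleted groups the counts were 229 for stereotypy against control, 0 between the TrkB-deleted groups (3063 at an unadjusted p under 0.05, and 0 by edgeR) and 620 for the F test. Fits to the 6 libraries compared gave 326 and 575 for the comparisons with the control. With single libraries left out, which also means fewer samples, the counts ranged from 124 to 803, 316 to 933, 0 to 1988, 414 to 732 and 545 to 2107.

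Ntrk2 kept its direction and call against the control under every alternative run, with left-out ranges of -3.43 to -3.12 with stereotypy, -4.49 to -4.14 without and -3.95 to -3.64 for both. Between the TrkB-deleted groups it ranged from 0.86 to 1.21 with libraries left out, and it missed the threshold with the glial and vascular covariate (0.70), after removal of the GC and length trend (0.94), with the other-neuron covariate (1.29) and without replicate 3 of both TrkB-deleted groups (1.05). Camera called 12, 20, 16 and 14 lists, in the order of the first 4 counts. With an estimated correlation it called 0 in each (adjusted p from 0.172), and fry called 3, 3, 0 and 2. Removal of the GC and length trend gave 20 lists for stereotypy against control, omission of replicate 3 of both TrkB-deleted groups 13 for no stereotypy against control, and the other-neuron covariate 9 between the TrkB-deleted groups; left-out ranges were 10 to 16, 13 to 22, 14 to 20 and 11 to 18. With the other-neuron covariate, which is built from the D2 MSN, cortical and interneuron markers and so fixes the outcome for those lists and in part for neuropeptides, the median turned for cortical markers (0.00305 with stereotypy and -0.0114 without, against control), interneuron markers (0.25 for stereotypy against control and 0.15 between the TrkB-deleted groups), and, between the TrkB-deleted groups, axon guidance (0.0701), cholesterol synthesis (0.48) and neuropeptides (0.0476). It also turned for nuclear respiratory chain subunits with stereotypy without replicate 3 of that group (0.0257) or of both TrkB-deleted groups (0.0256; left-out range -0.133 to 0.0257), for cholesterol synthesis between the TrkB-deleted groups without that pair (0.0597) and for dopamine and cAMP signalling in both groups without control replicate 1 (0.00577; left-out range -0.129 to 0.00577). The shared count of 269 was 500 at an adjusted p of 0.1, 122 without the filter, 435 with array weights, 9 with the glial and vascular covariate, 490 with DESeq2 and 145 without replicate 3 of both TrkB-deleted groups, with a left-out range of 97 to 268. Over all genes and lists named, 4319 of the recomputed gene values and 773 of the list values counted as unchanged. A call counted so when it kept its direction and side of the threshold. Genes not called with all libraries counted so when they stayed uncalled or when their sign changed. Direction was kept but the call lost, whatever the size, in 848 and 208, while 20 gene values gained a call and 11 list values turned. For fry and for camera with an estimated correlation the list medians were not recomputed, so their direction was fixed. At this depth, in simulated data, limma recovered 56.7% of genes changed 2-fold between the TrkB-deleted groups.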

Other observations

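The test of the region around Ntrk2 was chosen only after the result was seen. Genes tied by earlier work to stereotypy, tics or compulsion were lower in the group without stereotypy than in the control, with 2 of 21 fallen and 1 risen (1 higher and 6 lower when adjusted over the list alone). They had a median log2 change of -0.16, with camera adjusted p = 0.00804, and adjusted p = 0.361 with an estimated correlation. Their median was -0.0935 without control replicate 2. This list also passed for both TrkB-deleted groups against control, with a median of -0.0844 and camera adjusted p = 0.0269 (0.487 with an estimated correlation). It did not pass for stereotypy against control alone or between the TrkB-deleted groups. The glutamate transporter gene Slc1a1 fell from 165 ± 4.50 to 113 ± 2.05 CPM (SD, n = 3 each, limma adjusted p = 0.00465), and Slitrk1, a synaptic membrane protein, rose from 43.3 ± 10.5 to 87.7 ± 16.8 CPM (SD, n = 3 each, adjusted p = 0.00910). With stereotypy Slc1a1 stood at 133 ± 12.1 and Slitrk1 at 76.2 ± 5.11 CPM. For both TrkB-deleted groups against control Slc1a1 changed by -0.43 and Slitrk1 by 0.92 on the log2 scale (limma adjusted p = 0.0074 and 0.0076). Synaptic adhesion genes fell in 10 of 67 and rose in 2 without stereotypy (6 higher and 15 lower when adjusted over the list alone). The adhesion list had a median log2 change of -0.07, with camera adjusted p = 0.0114, and adjusted p = 0.668 with an estimated correlation. That call was lost without control replicate 3 (adjusted p = 0.225, range over the alternatives 0.000743 to 0.668). The adhesion median was -0.10 with rescaling, -0.15 without control replicate 2, -0.0339 without control replicate 3, -0.14 without no stereotypy replicate 3 and -0.15 with the covariate of other-neuron markers. The adhesion list also passed for both TrkB-deleted groups against control, with a median of -0.0362 and camera adjusted p = 0.0258. That call was kept in 10 of 16 settings.

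Genes of chromosome 13 near the targeted gene appeared among the genotype calls, with Cxcl14 and Shc3 within 10 Mb of Ntrk2, so differences carried along with the targeted region might have added calls. Of 133 tested genes in that window 10 were called for both TrkB-deleted groups against control (7.52%), against 5.70% elsewhere. This is a ratio of 1.32 (Fisher's exact test, two-sided, p = 0.346), with a 95% interval of the odds ratio from 0.627 to 2.57, so the counts are too few to decide and this stays open.

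Sex-linked genes, chosen after their values were seen, did not match within groups, and the labels give no sex. Xist was at 109 CPM in stereotypy replicate 3 and 17.9 CPM in no stereotypy replicate 3, and at most 4.21 CPM in the others. The Y-linked gene Ddx3y was at 0.959 and 5.03 CPM in those libraries and at 38.8 CPM or more in the others. Leaving out both libraries is among the alternatives.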
